A study of Mus musculus with 5 samples.

How the data were processed

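Primary microglia from mouse brain were profiled by RNA sequencing in 5 libraries, 2 labelled as carrying the inducible Cre at Cx3cr1 together with floxed Ythdf2 and 3 labelled as carrying floxed Ythdf2 alone. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra kit. The deposited table holds whole-number read counts per gene symbol, which the authors did not normalize as far as the values show. FastQC, STAR and HTSeq and the genome build mm10 are named per the submitters' processing notes, and their versions, the annotation and whether counting used strand are not given in the sources used here. The table lists 21983 genes, of which 15981 had at least 1 count in some library. Of these genes 21964 (99.9%) were matched by symbol to GENCODE release M21, which supplied coordinates on GRCm38, exon overlaps, transcript lengths and 3' untranslated regions. Groups and replicate numbers came from the sample titles, and the title of the third control carries 2 different numbers. Its library number was used.

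Total gene counts were 15743468 and 19577217 for the libraries labelled knockout 1 and 2 and 15565624, 15744558 and 13947500 for controls 1 to 3. The 10 most abundant genes took 7.24% to 14.2% of the counts, and mitochondrially encoded genes 1.16% to 2.2%. The spread between libraries gave a biological coefficient of variation of 0.408.

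The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), two-sided, with filterByExpr on the groups, TMM factors, robust estimation and the quasi-likelihood method of edgeR version 4 set explicitly. Benjamini-Hochberg adjustment ran over the 12543 genes tested, with a threshold of 0.05 and 3 residual degrees of freedom. CPM values use TMM-scaled library sizes, and log2 CPM values a prior count of 2. Lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 40 lists with at least 5 members tested, and again with an estimated correlation and with fry. A list's score in a library is the mean over members of log2 CPM minus the gene's mean over the 5 libraries. A count adjusted over the list alone applies Benjamini-Hochberg to the edgeR p-values of the list's members.

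The design, the 43 lists and the naming rule were fixed in advance. The rule named Ythdf2 and Cx3cr1 in any case, and the 12 largest rises and 12 largest falls among edgeR calls with a mean of at least 10 CPM, no overlap between groups and no provisional symbol. It also named up to 4 members of a list with the smallest p, or, where none was called, at most 2 with the highest mean. Since 0 genes met the rule for calls in edgeR (838 at an unadjusted p under 0.05, 232 called by DESeq2, 0 by limma-voom), the same rule was applied to the DESeq2 calls, and list members called by DESeq2 were named; some genes that met it are not reported here. This was chosen after the values were seen, when 56 higher and 57 lower genes met the rule.

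Alternatives fixed before the data were examined were other scalings (size factors of DESeq2, upper quartile, library totals), no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood method, no robust estimation, a replicate block, each library left out in turn, ribosomal, mitochondrial and haemoglobin genes left out, and a change of at least 2-fold. Chosen after seeing the data were a correction of each library for its loess trend (span 0.3) on transcript length, which 12538 genes had, an oligodendrocyte score as covariate, and DESeq2 with libraries left out or with the block.

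The steps were tested on simulated data with the real means, library sizes and gene-wise dispersions. In the simulation of this comparison, run on 12355 genes, edgeR recovered 0 of 67 genes changed 2-fold, 24 of 67 changed 4-fold and 49 of 66 changed 8-fold, with 8 unchanged genes called. DESeq2, with 12299 genes adjusted, recovered 5 of 67, 49 of 67 and 58 of 66, with 58 unchanged genes called. Camera recovered the list that had been shifted and called 1 other of 40. The simulated genes varied independently of each other, whereas the estimated correlation reached 0.951 in the interferon list of the real libraries. The simulation therefore does not show how often camera calls lists whose members move together. Lists for T, B and NK cells, erythroid cells and sex-linked transcripts had too few members tested and were not tested as lists.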

Results

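RNA sequencing was carried out on primary microglia, the resident macrophages of the brain, from mouse brain tissue. Ythdf2 encodes a cytoplasmic reader of N6-methyladenosine that directs marked mRNAs to decay. In the labelled knockout genotype a tamoxifen-inducible Cre recombinase, expressed from the Cx3cr1 locus that microglia use, is combined with Ythdf2 alleles flanked by loxP sites. The control genotype carries the floxed alleles alone. The labels give 2 libraries of the first kind and 3 of the second, and the comparison asks which processes and pathways differ in microglia without Ythdf2. Gene counts summed to 15743468 and 19577217 in the libraries labelled knockout 1 and 2, and to 15565624, 15744558 and 13947500 in controls 1 to 3. Counts were found for 13991 to 14673 genes per library. Every pair of libraries differed by far more than counting noise, with a chi-square of 56.2 to 287 per degree of freedom. The labels do not say whether the libraries come from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

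Ythdf2 itself did not fall in the libraries labelled knockout. It stood at 103.5 and 127 CPM (counts scaled to the size of each library) there, against 57.0, 69.2 and 68.8 CPM in the controls. The means were 115 ± 16.5 (SD, n = 2) and 65.0 ± 6.91 (SD, n = 3), a log2 fold change of 0.83 (SE 0.207). Cx3cr1, the fractalkine receptor gene, was lower in both, at 337 and 97.7 CPM against 682, 992 and 681 CPM, with a log2 fold change of -1.85 (SE 0.571) that was -3.04 without the library labelled knockout 1 and -1.22 without the library labelled knockout 2. For this pair of genes, chosen beforehand, the edgeR quasi-likelihood test gave adjusted p = 0.0151 for Ythdf2 and 0.0185 for Cx3cr1 when adjusted over the list alone. Adjusted over all genes tested, the edgeR values were 0.431 and 0.575. The Ythdf2 paralogs Ythdf1 and Ythdf3, which encode sister readers, had log2 fold changes of 0.03 (SE 0.192) and 0.08 (SE 0.196). Ythdf2 lies on chromosome 4 at 132184912 to 132212303 (minus strand, GRCm38, GENCODE M21, ENSMUSG00000040025.17), and no exon of another annotated gene overlaps its exons. Cx3cr1 lies on chromosome 9 at 119901616 to 120069879 (minus strand, ENSMUSG00000052336.7). Its exons overlap those of the antisense gene Gm33858, and whether counting used strand is not given in the sources used here. A gene-level count also takes reads from exons outside the deleted part, so it does not check the deletion. Because the targeted gene goes against its label, the libraries are called labelled knockout throughout, and every direction below is drawn from those labels.

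**Figure D1:**
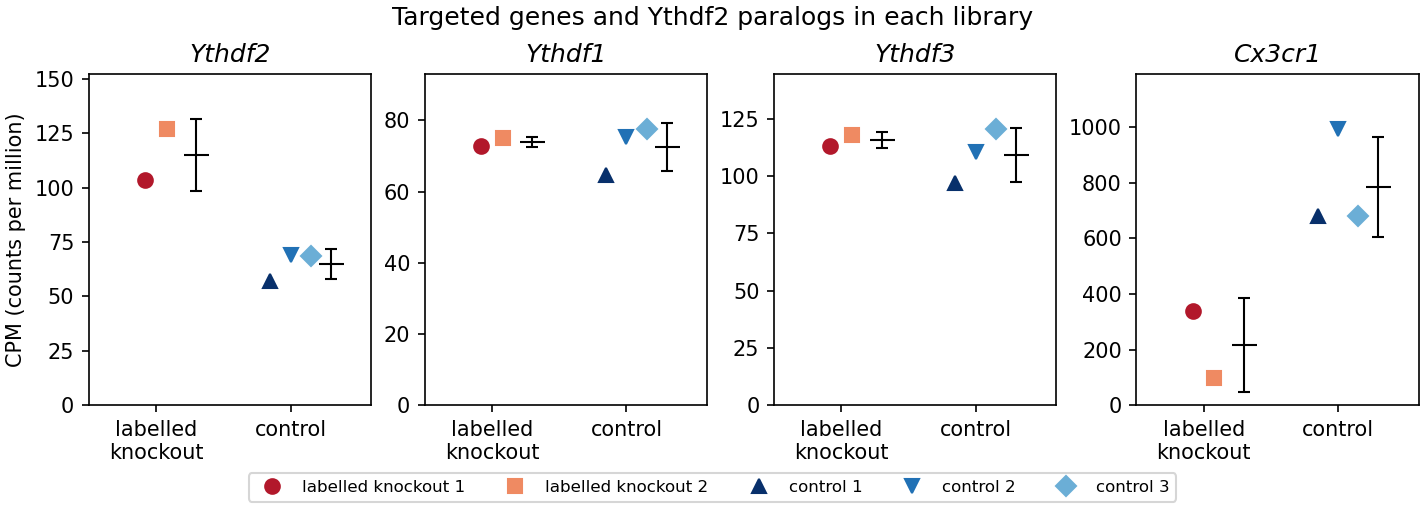
CPM of Ythdf2, its paralogs Ythdf1 and Ythdf3, and Cx3cr1 in each of the 5 libraries, 2 labelled knockout and 3 control; points are libraries and black bars the mean and SD of a group. Ythdf2 lies at 103.5 and 127 CPM in the libraries labelled knockout, above every control, and Cx3cr1 at 337 and 97.7 CPM, below every control.

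As groups, choroid plexus and monocyte genes were higher in the libraries labelled knockout, and immediate early and homeostatic microglia genes lower, also with each library left out in turn. Cell cycle genes were called higher and interferon-stimulated genes lower only with the library labelled knockout 1 included (camera adjusted p = 0.338 and 0.133 without it), and in both the scores of the controls overlapped those of the libraries labelled knockout. These group calls came from camera with a preset correlation and did not hold with an estimated one, where the smallest adjusted p was 0.426. No gene passed the edgeR quasi-likelihood test: 0 of 12543 genes reached an adjusted p under 0.05, and the smallest adjusted p was 0.231. At an unadjusted p under 0.05 edgeR found 838 genes, 500 higher and 338 lower, where chance would give 627. Other splits of the 5 libraries into 2 and 3 gave 28 to 2320 such genes, and 2 of those splits exceeded the real one. In limma-voom 0 genes passed, with 752 at an unadjusted p under 0.05, while DESeq2 called 232 genes, 146 higher and 86 lower, of which 228 differed by at least 2-fold. In libraries simulated with the real dispersions DESeq2 also called 58 unchanged genes, against 8 in edgeR, so its calls here can include false ones. Over all genes tested by edgeR, the 2 groups of libraries did not overlap for 1235 genes that were higher and 1308 that were lower. That is 20.3% of genes, against 20% by chance for 2 libraries against 3. The DESeq2 count moved with single libraries: 468 genes without the library labelled knockout 2, 87 without control 1 and 102 without control 2.

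Since edgeR called no gene, the same naming rule was applied to the DESeq2 calls after the values were seen; edgeR adjusted p was 0.231 or more for each gene named. The largest rises in DESeq2 included Slpi, a secreted protease inhibitor, at 5.53 and 60.2 CPM against 0.127 to 1.13 CPM in the controls (log2 fold change 6.01, SE 1.24). Arg1, the arginase of alternatively activated macrophages, stood at 34.8 and 154.5 CPM against 1.77 to 3.35 CPM (log2 fold change 5.32, SE 0.708; DESeq2 adjusted p = 8.46e-12). Atp2a3, a calcium pump of the endoplasmic reticulum, was at 51.2 and 43.6 CPM against 1.45 to 4.09 CPM. Il7r, the interleukin 7 receptor chain, was at 41.5 and 71.8 CPM against 5.05 to 8.55 CPM. Ace, Plcb2, Papss2, Atrnl1 and the mitotic genes Mki67, Cenpf and Aspm were also among these calls. Mki67, a marker of cycling cells, reached 789.9 CPM in the library labelled knockout 1 and 126 CPM in the other, against 33.0 to 115 CPM in the controls. The scavenger receptor gene Marco was at 1123 and 4054 CPM against 363 to 662 CPM (DESeq2 adjusted p = 0.00441). Single libraries moved these edgeR log2 fold changes: without the library labelled knockout 2 they were 3.43 for Slpi, 3.88 for Arg1 and 1.22 for Marco, without the library labelled knockout 1 that of Mki67 was 0.90, and without control 1 that of Slpi was 7.515.

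Among the DESeq2 calls that were lower, Postn, a matrix protein of fibroblasts, stood at 0.476 and 0.649 CPM against 50.4, 58.9 and 13.2 CPM in the controls (log2 fold change -6.16, SE 0.885; DESeq2 adjusted p = 3.54e-13). Apoc1, an apolipoprotein gene, was at 0.297 and 3.62 CPM against 15.5 to 34.95 CPM, and Lpl, the lipoprotein lipase gene, at 1994 and 2590 CPM against 4600 to 6894 CPM. Plin2, which coats lipid droplets, was 2.65-fold lower by group means, and Hmox1, the haem-degrading enzyme gene, 2.63-fold lower. Cd14, a co-receptor for lipopolysaccharide, was at 171 and 376 CPM against 660 to 1409 CPM (DESeq2 adjusted p = 0.00794). Vegfa, the main angiogenic growth factor gene, was at 9.87 and 24.2 CPM against 34.3 to 124 CPM (DESeq2 adjusted p = 0.0342, edgeR adjusted p = 0.565). Sall3, Ifi205, Cyr61, Dusp1, Slco2b1, Ptchd1, Serpine2, Cd72 and Kitl were also among the largest falls in DESeq2. Exons of Ace, Dusp1, Slco2b1, Ptchd1, Cd72, Kcnj13, Otx2 and F13a1 overlap genes annotated on the other strand, so their counts can include reads of those genes. Exons of Slpi and Otx2 also overlap a gene annotated on the same strand, which counting by strand would not separate.

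Of 43 gene lists fixed beforehand, 40 had at least 5 members tested, and camera with its preset correlation called 17, 3 upward and 14 downward. None of the 17 held with a correlation estimated from these libraries, where the smallest adjusted p was 0.426. Counts over all genes tested were 0 in every list by edgeR, and the counts adjusted over the list alone are given with each list. Median, mean and test had the same sign in each of the 17 lists. 5 of the lists called by camera were kept without each library in turn: ependymal and choroid plexus markers, immediate early genes, homeostatic microglia, monocyte markers and the unfolded protein response.

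Ependymal and choroid plexus markers showed the largest shift, upward, with a median log2 fold change of 3.61 (camera adjusted p = 9.34e-17). The adjusted p = 0.426 with an estimated correlation. Of its 8 members tested, 6 lay above every control in both libraries labelled knockout, where chance gives 10%, and 6 passed edgeR adjusted over the list alone. Ttr, the transthyretin gene of choroid plexus epithelium, was at 101 and 203 CPM against 22.1, 5.89 and 24.8 CPM. Clic6, a chloride channel gene of the same epithelium, was at 25.1 and 5.67 CPM against 0.127 to 0.372 CPM. Kl, Kcnj13, Folr1 and Otx2, other genes of this epithelium, were at 0.919 to 9.93 CPM against 0 to 1.01 CPM, while the ciliary genes Foxj1 and Cfap126 overlapped between groups.

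**Figure D2:**
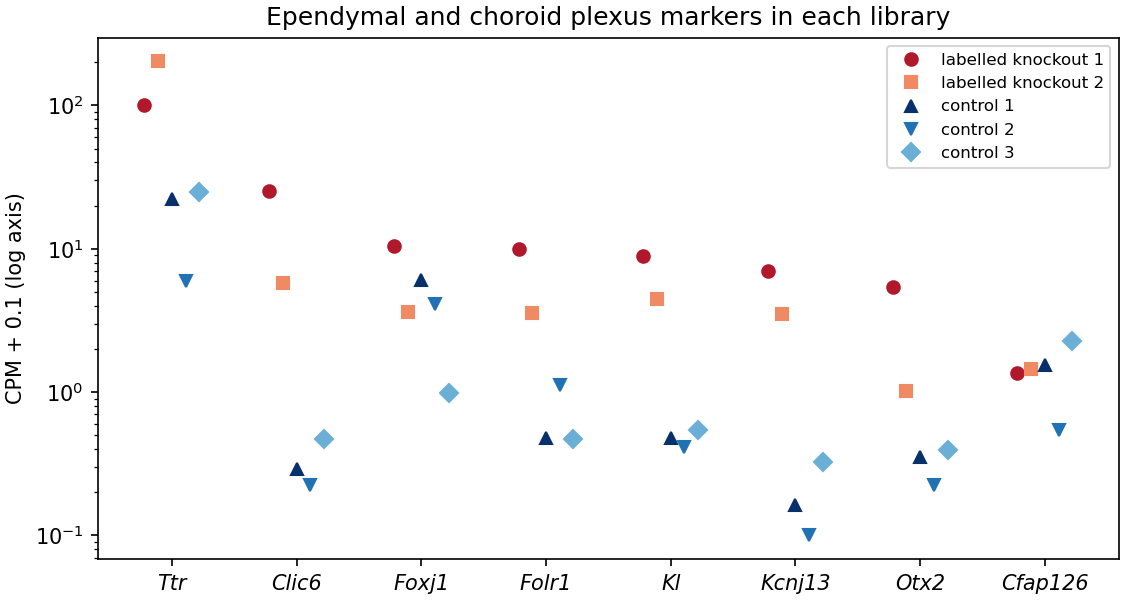
CPM, with 0.1 added, on a log axis, for the 8 ependymal and choroid plexus markers tested; each point is 1 of the 5 libraries. 6 of the 8 genes lie above every control in both libraries labelled knockout, and Foxj1 and Cfap126 overlap.

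Monocyte markers were higher as a group, with a median log2 fold change of 0.44 over 9 genes (camera adjusted p = 0.00466). For this list too the adjusted p = 0.426 with an estimated correlation. In it, 4 members were higher and 1 lower adjusted over the list alone, and the log2 fold change was positive in 7 and negative in 2. Ms4a4c, the member with the second highest mean, had a log2 fold change of -2.84 (SE 1.73) and overlapped between groups. Ace, an enzyme of the angiotensin system, was at 38.5 and 13.1 CPM against 0.943 to 2.45 CPM, and Spn, a sialophorin gene, at 15.2 and 8.32 CPM against 1.51 to 2.79 CPM. Choroid plexus markers separated the libraries the same way. Cell cycle and DNA replication genes were also higher as a group, with 52 of 59 positive and a median log2 fold change of 0.72 (camera adjusted p = 1.59e-09). This became adjusted p = 0.73 with an estimated correlation, and it was 0.338 by camera without the library labelled knockout 1. Its mean log2 score per library was 1.09 in that library, -0.05 in the other, and 0.46 in control 3, so 1 control exceeded a library labelled knockout. 0 of its members passed edgeR adjusted over the list alone.

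Immediate early and dissociation-response genes, which are switched on within minutes by stimulation or handling of cells, were lower as a group (median log2 fold change -0.87, camera adjusted p = 4.13e-13). The log2 fold change was negative in 33 of 34 members, and 14 lay below every control in both libraries labelled knockout, where chance gives 10%. With an estimated correlation the adjusted p = 0.426, and 2 members were lower adjusted over the list alone. Fos, a subunit of the AP-1 transcription factor, was at 24.9 and 26.8 CPM against 157, 117 and 116 CPM (log2 fold change -2.33, SE 0.247; DESeq2 adjusted p = 1.59e-10). Egr1 was at 22.96 and 32.4 CPM against 95.5 to 129.5 CPM, and Dusp1, a phosphatase gene that limits MAP kinase signalling, at 3.99 and 11.5 CPM against 30.1 to 92.3 CPM. The libraries lowest in these genes are those with the choroid plexus signal.

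Homeostatic microglia genes went both ways, though the list fell as a whole (27 tested, median log2 fold change -0.50, camera adjusted p = 5.1e-07). Camera gave adjusted p = 0.426 with an estimated correlation, and 6 members were lower adjusted over the list alone. Choroid plexus and monocyte markers were higher in the same libraries, with scores of 2.32 and 1.27 for the first and 0.28 and 0.78 for the second. Fcrls and Olfml3 were 4.17-fold and 4.31-fold lower by group means, and Csf1r, the growth factor receptor microglia depend on, overlapped between groups at 2416 and 3154 CPM against 2372 to 4220 CPM. Egr1, which was lower, is a member of both this list and the immediate early list, so it counts in each. In 3 of the 27 members both libraries labelled knockout lay above every control, and in 9 below, where chance gives 10% in each direction. The number above is near that share. The 3 higher ones, picked out after their values were seen, were P2ry12, P2ry13 and Tmem119, surface proteins used as markers of resting microglia, with log2 fold changes of 1.08, 1.23 and 1.61 and edgeR adjusted p of 0.802, 0.669 and 0.575. The unfolded protein and integrated stress response list was lower with a median of only -0.13 (30 tested, camera adjusted p = 0.00692). Again the adjusted p = 0.426 with an estimated correlation, and 0 members were higher and 1 lower adjusted over the list alone. Trib3, a target of the ATF4 arm, was 3.76-fold lower by group means. Asns, another such target, was at 50.1 and 20.1 CPM against 127, 177 and 83.3 CPM, and its log2 fold change of -1.88 was -2.71 without the library labelled knockout 1 and -1.37 without the library labelled knockout 2. Calr and Hspa5, chaperones of the endoplasmic reticulum, had log2 fold changes of 0.37 and 0.30.

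Interferon-stimulated genes were negative in 45 of 46 members (median log2 fold change -1.02, camera adjusted p = 2.89e-12), with 0 members adjusted over the list alone. With an estimated correlation the adjusted p = 0.725. The list rested on single libraries: its score was -1.77 in the library labelled knockout 1, 0.33 in the other, and 0.15, -0.18 and 1.48 in controls 1 to 3. Without the library labelled knockout 1 the camera adjusted p was 0.133. MHC class I genes (median -0.68), pro-inflammatory cytokines and chemokines (-1.10), cholesterol efflux and lipid handling (-0.28), oxidative stress response (-0.28) and angiogenic and vascular factors (-0.08) were called downward by camera with adjusted p of 4.4e-05, 0.000137, 0.000454, 0.000454 and 0.0101. Their adjusted p with an estimated correlation was 0.725, 0.725, 0.563, 0.725 and 0.563. None of these 5 stayed called without the library labelled knockout 1, where camera gave adjusted p of 0.255, 0.917, 0.226, 0.347 and 0.226; the cytokine list was also lost without control 3 (adjusted p = 0.0708). Adjusted over the list alone, 1 cytokine gene and 0 genes of the other 4 lists passed edgeR. The cytokine list member was Ptgs2, the inducible cyclooxygenase gene, at 3.39 and 2.38 CPM against 12.3 to 17.1 CPM.

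Disease-associated microglia genes (median -0.29), cytosolic ribosomal proteins (-0.11) and NF-kB and Toll-like receptor genes (-0.19) were called downward with camera adjusted p of 0.0124, 0.0169 and 0.0193, and 0.822, 0.913 and 0.822 with an estimated correlation. Without the library labelled knockout 1 their medians turned positive, to 0.13, 0.33 and 0.06. For the ribosomal list the call itself turned, upward without the library labelled knockout 1 (camera adjusted p = 0.000418) and downward without the library labelled knockout 2 (7.43e-12). This list was also lost without control 1 (adjusted p = 0.0759), without control 3 (0.376) and after a correction for transcript length (0.533), and the NF-kB list without control 3 (0.238). 0 members of these lists passed edgeR adjusted over the list alone. Apoe, a lipid carrier gene of activated microglia, was at 2038 and 21500 CPM in the libraries labelled knockout against 28440, 11270 and 13790 CPM. Hypoxia and glycolysis genes (median -0.18, camera adjusted p = 0.00107) had an adjusted p = 0.563 with an estimated correlation and 0.148 without the library labelled knockout 2, with 0 members adjusted over the list alone. Mural cell and fibroblast markers (median -1.54, camera adjusted p = 0.00131) had an adjusted p = 0.725 with an estimated correlation. Camera no longer called them without the library labelled knockout 2 (0.151), control 1 (0.227) or control 2 (0.0581). In this list 2 members were higher and 2 lower adjusted over the list alone, and Dcn, a matrix proteoglycan gene, was at 0 and 0.27 CPM against 7.92, 6.65 and 0.595 CPM.

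**Figure D3:**
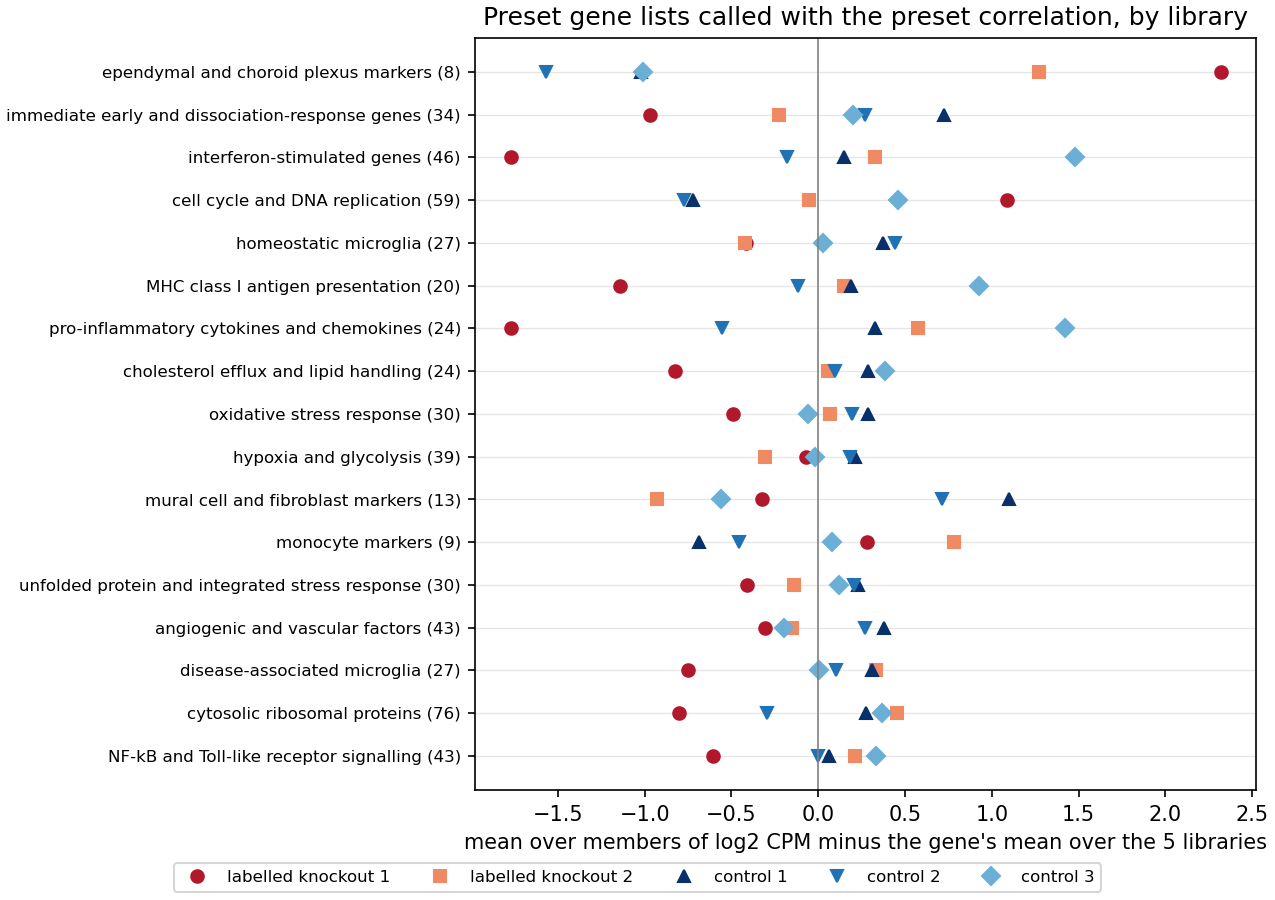
Score of each of the 17 lists called by camera with its preset correlation in each of the 5 libraries, on a log2 scale relative to the mean of the libraries; the number of members tested is in parentheses. The choroid plexus list separates the groups most widely, while the interferon list runs from -1.77 in the library labelled knockout 1 to 1.48 in control 3 with the other libraries between.

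The remaining 23 lists were not called by camera, with adjusted p from 0.0519 (cell migration and chemokine receptors) to 0.959. The m6A writers, erasers and readers (23 tested) had a median log2 fold change of 0.03 and a mean of -0.07 with a downward test (camera adjusted p = 0.614). The deadenylation and decapping genes through which YTHDF2 acts had a median of -0.02 (adjusted p = 0.371). Sterol and fatty acid synthesis had a median of -0.09 and a mean of 0.08 with a downward test (adjusted p = 0.889), and astrocyte markers a median of -0.03 with an upward test (adjusted p = 0.614). Of the other cell types, oligodendrocyte lineage markers (median 0.31, adjusted p = 0.15), neuron markers (0.96, 0.273), neutrophil markers (1.03, 0.351), endothelial markers (-0.52, 0.959) and border-associated macrophage markers (0.15, 0.155) were not called with all libraries. Without the library labelled knockout 1 camera called neutrophil and border-associated macrophage markers upward (adjusted p = 1.56e-06 and 5.49e-06), the latter also without control 3 (0.0271). Oligodendrocyte markers were called upward without the library labelled knockout 2 (0.00398), control 1 (0.00333) or control 2 (0.00521), and neuron markers without the library labelled knockout 2 (0.0345). Oligodendrocyte transcripts were uneven between libraries: the score of the list was 1.14 and -0.52 in the libraries labelled knockout and 0.72, 0.75 and -2.08 in controls 1 to 3. Vwf, the von Willebrand factor gene of endothelium, was at 55.6 and 81.8 CPM against 8.25 to 18.6 CPM (DESeq2 adjusted p = 0.000117, edgeR adjusted p = 0.262). Of 20 markers of T, B and NK cells and 10 of erythroid cells, 2 and 0 were tested, and Cd4 was at 73.7 CPM in control 3 against 4.31 to 9.28 CPM in the other libraries. The T cell genes Cd3d, Cd3e, Cd3g, Cd8a and Cd8b1 had 0 CPM in every library, control 3 included.

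Libraries did not group by label alone. The first principal component, 53% of the variance, placed the library labelled knockout 1 at -82.2 and control 3 at 71.7, with the other 3 libraries between. The second, 26.7%, separated controls 1 and 2 (41.65 and 44.6) from control 3 (-15.8) and the libraries labelled knockout (-33.4 and -37.05).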

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

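The length correction, the oligodendrocyte covariate and the DESeq2 alternatives were chosen after seeing the data. With the oligodendrocyte covariate edgeR called 0 genes, with 1326 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0522. After the length correction edgeR also called 0, with 981 at an unadjusted p under 0.05 and a smallest adjusted p of 0.168. The edgeR count stayed at 0 under every scaling, filter, dispersion method, gene exclusion and left-out library run, with 407 to 2183 genes at an unadjusted p under 0.05 in those fits without 1 library. It was 232 in DESeq2 and 4 with the replicate block, whose 4 genes were Postn, Atp2a3, Arg1 and Ctgf (chosen after their values were seen). Ctgf overlapped between groups, at 2.56 and 1.73 CPM in the libraries labelled knockout against 53.2, 40.0 and 2.16 CPM in controls 1 to 3. Same-numbered libraries deviated with r of 0.148 and -0.562, and control 3, whose title also carries the number 2, with r of 0.473 to the library labelled knockout 2. With 2 libraries labelled knockout these values mirror each other by construction, so they do not show whether the numbers pair libraries. The block also ended the calls of the cytokine (adjusted p = 0.0714), ribosomal (0.238) and NF-kB (0.133) lists, and added calls of 4 lists: MHC class II (0.00418), integrins and matrix (0.000225), border-associated macrophages (0.0123) and oligodendrocytes (0.0284). Control 3 had no partner in the block, so it did not enter the genotype contrast there. Leaving control 3 out of the unblocked fit ended the same calls. It also added MHC class II (camera adjusted p = 0.0271), integrins and matrix (0.00111) and border-associated macrophages (0.0271), but not oligodendrocytes (0.127). Of the 23 lists not called with all libraries, 15 were called with at least 1 library left out. The DESeq2 count ran from 87 to 468 with 1 library left out and was 151 with the block. With 1 library labelled knockout left, that library is assumed to vary like the others. Of the DESeq2 calls, 95 were also called without the library labelled knockout 1 and 207 after the length correction. Lists called went from 17 to 0 with an estimated correlation, 0 by directional fry and 7 by mixed fry. Ythdf2 stayed positive (0.67 to 0.94) and Cx3cr1 negative (-3.04 to -1.22) in every setting run. No named gene reversed. For genes, a reversal was a change of sign with either setting past the threshold or the main value larger in size than its SE. Medians reversed without the library labelled knockout 1, with these lowest and highest values over left-out libraries: disease-associated microglia -0.83 and 0.13, ribosomal proteins -0.88 and 0.33, NF-kB -0.513 and 0.0578, oxidative phosphorylation -0.63 and 0.30, lysosome -0.58 and 0.27, alternative activation -0.73 and 0.0646, complement -1.18 and 0.42. Beside the ribosomal list, 4 of these, not called with all libraries, were called in opposite directions: oxidative phosphorylation, lysosome, complement and alternative activation were called upward by camera without the library labelled knockout 1 (adjusted p = 0.00024, 0.000371, 0.000418 and 0.0126) and downward without the library labelled knockout 2 (5.81e-07, 1.99e-05, 0.000802 and 0.00947). The oligodendrocyte median was -0.28 with the block, where the list was called, against 0.31 without it, while 3 of the left-out libraries gave an upward call. The cause of these changes was not tested. In simulated libraries of the same depth and spread edgeR recovered 0 of 67 genes changed 2-fold, 24 of 67 changed 4-fold and 49 of 66 changed 8-fold. With a low spread it recovered 56 of 67 changed 2-fold. DESeq2 recovered more at the real spread (5 of 67, 49 of 67 and 58 of 66) but called 58 unchanged genes, against 8 in edgeR. Why no gene passed edgeR in the real libraries was not tested.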

Other observations

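Tests chosen only after the result was seen are those on Cx3cr1 for swapped labels and both tests on oligodendrocyte RNA; the second of these was added because the first did not decide. Among the DESeq2 calls were several receptor and regulatory genes. Colec12, a scavenger receptor gene, was at 735 and 979 CPM against 431 to 459 CPM (DESeq2 adjusted p = 0.0398, edgeR adjusted p = 0.425). Ccr1, a chemokine receptor gene, was at 46.3 and 149 CPM against 19.8 to 33.4 CPM, and F13a1, a coagulation factor gene of border macrophages, at 79.1 and 185 CPM against 23.9 to 47.0 CPM. Zmat3, a p53 target gene, was 2.11-fold higher by group means, and Stat4, whose exons overlap a gene on the same strand, was at 6.37 and 4.32 CPM against 1.04 to 1.33 CPM. The Y-linked gene Ddx3y was at 33.6 and 62.4 CPM in the libraries labelled knockout and at 40.4, 52.5 and 14.3 CPM in the controls, so it was detected in all 5 libraries.

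Ythdf2 counts were higher, not lower, in the libraries labelled knockout. A swap of the 2 groups' labels would put the Cre-carrying Cx3cr1 locus in the other group, yet Cx3cr1 was lower where the label places it, with a log2 fold change of -1.85, more than 2 standard errors below 0, although edgeR gave adjusted p = 0.575 over all genes and the value ran from -3.04 to -1.22 with 1 library left out. Reads from a paralog or an overlapping gene were argued against by the highest log2 fold change among those, 0.0818 in Ythdf3, which lies below that of Ythdf2 by 0.74 (SE 0.285). Whether a transcript of the recombined allele is still counted stays open, because the table holds 1 Ythdf2 value per library and no exon counts, and a biological rise of the transcript stays open, untested. Incomplete recombination alone would leave Ythdf2 at the control level at most. Together with spread between libraries it stays open, because 1235 of 12543 genes lay above every control. Over all genes edgeR gave Ythdf2 an adjusted p = 0.431.

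Choroid plexus genes were higher in the libraries labelled knockout, and a hypothesis is that choroid plexus tissue may have been carried into these preparations. In a second list of 28 such genes, fixed before its values were seen, 24 were tested, 20 lay above every control (chance gives 10%), and the median log2 fold change was 3.79, although Enpp2, Slc12a2, Stk39 and Cab39l were also at 14.35 CPM or more in every control. The length correction left the preset list at a median of 3.83 (lower quartile 2.74), which argues against transcript length. The 2 libraries differed in level, with a median ratio of library 1 to library 2 of 3.39 in the second list, while Ttr, the most abundant member of the preset list, ran the other way at 0.499, so 1 tissue share does not account for Ttr. Carry-over and an effect of the genotype stay open, since both follow the same 2 libraries.

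The widest axis between libraries crossed the labels. Of the 10 splits of the 5 libraries into 2 and 3, too few for a share under 0.05, the real one gave 232 DESeq2 calls and the highest other, the library labelled knockout 2 with control 3, gave 856, which points to a structure of the samples. The length correction lowered the split of the library labelled knockout 1 with control 2 from 633 calls to 75, but that of the library labelled knockout 2 with control 3 still gave 899 calls, against 248 for the real one, so transcript length accounts for part of the structure at most. Oligodendrocyte and interferon scores ran in exactly opposite order over the 5 libraries, and after the part following the oligodendrocyte score was removed the interferon list spanned 0.795 log2 units between controls (1.66 before), which does not decide whether the 2 are linked. The 102 members of the homeostatic microglia, phagocytosis and lysosome lists had a mean slope on that score of -0.0568 (95% interval over genes -0.121 to 0.00705). The interferon list had -0.759, so on average these genes did not fall with the score as steeply. The interval does not measure the spread between the 5 libraries, and lysosome genes are not particular to microglia. Dilution of microglial RNA is therefore not decided, and a difference in preparation or activation state stays open.

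If loss of YTHDF2-directed decay had raised its targets, genes rich in m6A consensus motifs in the 3' untranslated region may have shifted upward in the libraries labelled knockout. Across 11330 genes, which are not independent replicates, the partial Spearman correlation of fold change with motif density, with 3' untranslated region length, transcript length and GC content removed, was 0.00504. The highest of the other splits gave 0.0163, and 4 of the 10 splits, the real one included, gave a correlation as large. These libraries therefore gave no sign of the predicted shift. Motifs stood in for m6A, which was not measured here, and the loss of Ythdf2 was not checked. The test therefore does not decide whether targets of YTHDF2 rose.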
